A study of Homo sapiens with 4 samples.

How the data were processed

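Small RNA of H661 cells was sequenced in 4 libraries, 2 from cells given DMSO and 2 from cells given 2.5 µM entinostat for 8 h. Per the labels' protocols, cells grew in RPMI1640 with 10% fetal bovine serum, RNA was taken with TRIzol, and libraries were made from 1 µg of total RNA with New England Biolabs small RNA reagents. Such kits ligate adapters to RNA ends and amplify by PCR, so recovery can differ between sequences. No molecular identifier is named in the labels, so the intervals of library shares and the limits of a count of 0 cover counting error only. Per the submitters' processing notes, bcl2fastq 2.18 was used. The aligner, the counting tool, the miRNA annotation and the genome build are not given in the sources used here, nor is any rule for reads shared by near-identical miRNAs. Members of one family that differ by few bases are therefore uncertain singly. Among the 319 rows with 100 or more counts in all, miR-365a-3p and miR-365b-3p had the same 4 counts, 0.131% of all counts.

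The deposited counts are whole numbers per mature miRNA name, with 826 rows and 1 column per library. The deposited CPM table holds the authors' values, which equal the count divided by the column total and multiplied by 1e+06, within 0.0001 CPM in 100% of rows, with no composition factor. Names were unique, so no rows were merged. Groups and replicate numbers came from the sample titles. No label says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

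Counts were scaled by the trimmed mean of M-values (TMM) and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with treatment as the only term. Levels are TMM-scaled CPM. Rows were kept by filterByExpr with its defaults (minimum count 10, minimum total 15), which left 401 rows tested and 425 not tested. A miRNA was called at a Benjamini-Hochberg adjusted p under 0.05, and fold changes are entinostat over DMSO with 95% intervals from the fitted standard error. The common dispersion was 0.00648, a biological coefficient of variation of 8.05%. Totals ran from 547875 to 938559 counts per library. The spread between libraries enters the fitted standard error, whose median was 0.0936 log2 units at 1000 CPM or more and 0.176 over all tested rows.

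The test was checked on simulated tables with the real means, totals and dispersion, 10 tables for each setting. With 200 of 401 rows changed, it found 57.9% of those changed 1.5-fold, 84.7% at 2-fold and 95.4% at 3-fold, and 93.7 to 94.9% of the intervals held the true value. With 20 rows changed, 92 to 92.5% of the intervals did. For the list test, in 50 tables, all lists of 10 rows shifted 1.3-fold and 6% of unshifted lists had an unadjusted camera p under 0.05. Rows were drawn independently there, and p was not adjusted over lists. These shares therefore do not give the power for the real lists, whose members can be correlated and whose p was adjusted.

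The tests, the miRNAs to name, 27 miRNA lists and most alternatives were fixed before the data were examined. Lists were families, clusters and literature sets recalled without a database, among them let-7, miR-17~92, DLK1-DIO3, p53-linked, histone deacetylase inhibitor-linked and lung cancer-raised miRNAs. Markers of neurons, muscle, mesenchyme, blood, liver and placenta were included for other cell types. A row joined a list by its name without arm and copy number. Lists with 3 or more tested members were tested with camera of limma 3.58.1 (preset correlation 0.01, two-sided), with an estimated correlation and with fry beside it. Named miRNAs were, with 0 called, the 5 of lowest unadjusted p in each direction, given as not past the threshold. The 5 most abundant, 12 fixed miRNAs and up to 4 members of lowest p of each list were added. If miRNAs had been called, up to 10 per direction would have been named by size of change.

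Arm pairs were formed by the miRNA name without its arm, each counted as 1 hairpin. They were compared by Pearson and Spearman correlation across hairpins with 100000 permuted pairings. Library shares have exact Clopper-Pearson 95% intervals, and a count of 0 was taken to allow 3 counts. Group differences in library composition were tested by exact permutation. Hairpin positions were looked up by name in GENCODE release 29 (GRCh38), which need not be the annotation the authors used. Alternatives covered scaling (size factors of the DESeq2 kind, upper quartile factors, library size alone), the low-count filter (none, or a mean CPM of 10 or more) and the tool (DESeq2 1.42.0, limma-voom, the edgeR likelihood ratio test). Further alternatives were a replicate block, each replicate left out, the 5 most abundant miRNAs left out, and limma-trend on the authors' deposited CPM, as log2 of the value plus 1 or 0.5. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for the rest.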

Results

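Mature microRNAs (miRNAs) were profiled by small RNA sequencing in H661, an established human line of large cell lung carcinoma. The cells received either the solvent dimethyl sulfoxide (DMSO) or 2.5 µM entinostat, a benzamide inhibitor of class I histone deacetylases, for 8 h. Each treatment had 2 libraries, and the design asked how miRNA abundance differed between the treatments. The count table listed 826 mature miRNAs. The libraries were shallow, at 938559 and 561485 miRNA counts with DMSO and 547875 and 753104 with entinostat. At least 1 count was seen for 687 and 596 miRNAs with DMSO and for 589 and 682 with entinostat. Levels are in CPM, counts per 1e+06 counts of a library after TMM scaling, and shares and limits use the unscaled totals. A count of 0 allowed up to 3.20 and 5.34 CPM in the DMSO libraries and up to 5.48 and 3.98 CPM in the entinostat libraries.

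The miRNA counts of H661 cells were dominated by the miR-99, miR-100 and miR-125 families and clusters. Recovery can differ between sequences, so a share of counts need not equal a share of the miRNA in the cells. The intervals of shares cover counting error only. The 10 listed members held 38.3% and 38.1% of the counts with DMSO and 38.0% and 38.0% with entinostat. A single miRNA, miR-99a-5p, took 25.2% of one DMSO library (exact 95% interval 25.2 to 25.3%) and 26.4% of the other (26.3 to 26.6%). With entinostat its share was 27.3% (27.2 to 27.4%) and 26.2% (26.1 to 26.3%). The hairpin of miR-99a lies in an intron of the long non-coding RNA gene MIR99AHG (chromosome 21, 16539089 to 16539169, plus strand, GRCh38). The miR-30 family made up 10.7% and 10.4% of the counts with DMSO and 10.8% and 10.6% with entinostat. The 10 most abundant miRNAs together held 55.8 ± 0.520% of the counts with DMSO and 55.5 ± 0.117% with entinostat (SD, n = 2). Neither this share, nor that of the top miRNA, nor the total count, nor the number of miRNAs with a count differed by more than regrouping of the libraries gave (two-sided exact permutation test, p = 0.667 for each). With 2 libraries against 2, that test cannot go below 0.333.

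How far entinostat libraries lay from DMSO libraries, relative to libraries of one treatment, depended on the abundance of the miRNAs compared. Over the 97 miRNAs of 1000 CPM or more, the root mean square log2 difference was 0.12 between the DMSO libraries and 0.19 between the entinostat libraries. The pairs across treatments ranged from 0.0966 to 0.196, with a mean of 0.163, against a mean of 0.156 within treatments. Among these miRNAs the closest pair was DMSO replicate 2 with entinostat replicate 1. Over the 237 miRNAs of 100 CPM or more, the DMSO pair was the closest at 0.196 and the entinostat pair was at 0.235. The pairs across treatments were then at 0.216, 0.244, 0.250 and 0.253. DMSO replicate 2 and entinostat replicate 1, the pair at 0.216, had the lowest totals, at 561485 and 547875 counts. Counting noise weighs most on that pair at lower abundance, so depth and treatment cannot be told apart in this change of order. Both within-treatment pairs differed by more than sampling noise, with a chi-square of 5.93 per degree of freedom for DMSO and 7.51 for entinostat, so neither pair was treated as 1 library deposited in duplicate. Libraries made from 1 culture could also differ this much.

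**Figure D1:**
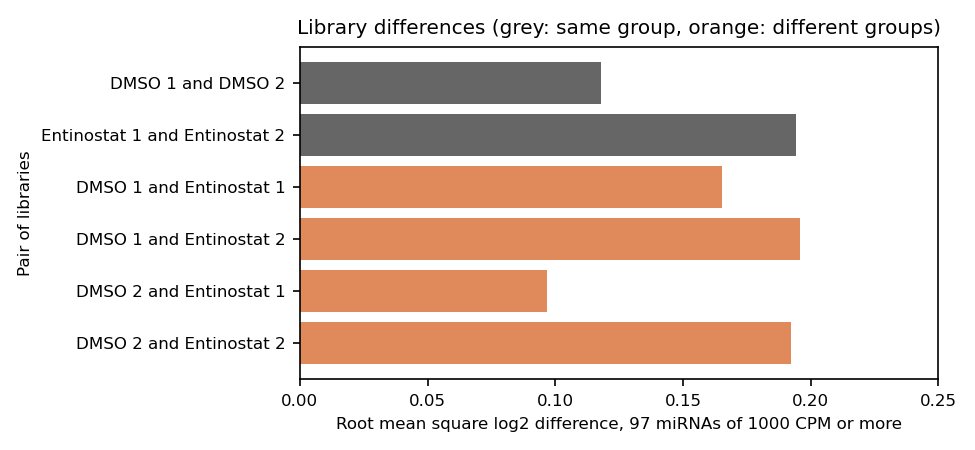
Root mean square log2 difference in abundance between each pair of libraries (x axis, log2 units) over the 97 miRNAs of 1000 CPM or more, with the pairs on the y axis; each bar is 1 pair, grey within a treatment and orange across treatments. The across-treatment bars run from 0.0966 to 0.196 and enclose both within-treatment bars.

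Relative to the other miRNAs of a library, the most abundant miRNAs kept close to their DMSO level after 8 h of entinostat. No added reference RNA entered the scaling, so a rise or fall of the whole miRNA pool would not be seen. Abundance of miR-99a-5p was 259067 ± 7716 CPM with DMSO and 267472 ± 10658 CPM with entinostat (SD, n = 2), a log2 fold change of 0.05 with a 95% interval of -0.10 to 0.19. The level of miR-99b-5p was 53492 ± 6842 CPM against 46037 ± 3907 CPM, a log2 fold change of -0.22 (-0.45 to 0.01), which was -0.08 without DMSO replicate 1 and -0.35 without DMSO replicate 2. For miR-30c-5p and miR-125b-5p the log2 fold changes were -0.07 (-0.24 to 0.09) and -0.07 (-0.24 to 0.10), and both turned positive when libraries were scaled by upper quartile factors. For miR-30a-5p the value was 0.13 (-0.03 to 0.28). All 97 miRNAs of 1000 CPM or more had a 95% interval inside a 1.5-fold change in either direction, but 91 did with upper quartile factors and 91 without entinostat replicate 1. Of the 237 miRNAs of 100 CPM or more, 198 had an interval inside 1.5-fold and 233 inside 2-fold. Over all 401 tested miRNAs, the interval lay inside 2-fold for 295, and for the others a change of that size was not excluded. These intervals hold for each miRNA singly, not for all jointly.

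No miRNA passed an adjusted p of 0.05 between entinostat and DMSO. The edgeR quasi-likelihood test called 0 of the 401 tested miRNAs higher or lower, with a lowest Benjamini-Hochberg adjusted p of 0.316. At an unadjusted p under 0.05 it gave 27 miRNAs, 12 higher and 15 lower, where 20.05 would arise by chance. DESeq2 and limma-voom also called 0, with 11 and 31 miRNAs at an unadjusted p under 0.05. DESeq2 took all 826 listed miRNAs and limma-voom the 401 tested, so the 11 cannot be set against 20.05. With upper quartile factors, which moved the median log2 fold change of all tested miRNAs from 0.00466 to 0.12, those 12 higher and 15 lower became 38 higher and 6 lower, and 0 were called. In 163 miRNAs (83 higher, 80 lower) the libraries of the treatments did not overlap, 40.6% of those tested against 33.3% by chance. The count of 0 held in the quasi-likelihood test but not with an edgeR likelihood ratio test, which called 4 miRNAs, nor without entinostat replicate 1, where 6 were called. In simulated tables of this depth and spread with 20 changed miRNAs, the test found 38% of those changed 1.5-fold, 66% of those changed 2-fold and 82% of those changed 3-fold.

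**Figure D2:**
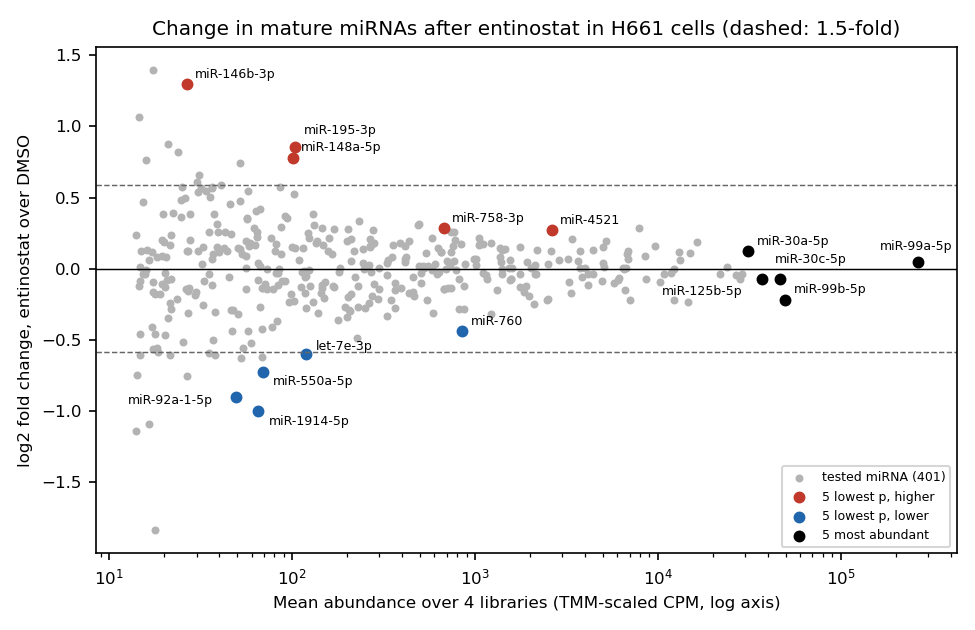
Log2 fold change of entinostat over DMSO (y axis) against mean abundance in TMM-scaled CPM on a log axis (x axis) for the 401 tested miRNAs; each point is 1 miRNA, with the 5 of lowest p in each direction in red and blue, the 5 most abundant in black, and dashed lines at 1.5-fold. The spread narrows with abundance, and none of the coloured miRNAs passed an adjusted p of 0.05.

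The miRNAs with the lowest p on the higher side were mostly of low abundance, and none passed the threshold. The level of miR-148a-5p was 74.2 ± 3.46 CPM with DMSO and 127.0 ± 2.56 CPM with entinostat (SD, n = 2), a fold of 1.72 (log2 fold change 0.78, SE 0.18, edgeR adjusted p = 0.316). Its hairpin is intergenic (chromosome 7, 25949919 to 25949986, minus strand, GRCh38). The level of miR-195-3p, from the host transcript MIR497HG (chromosome 17, 7017615 to 7017701, minus strand), was 74.9 ± 15.1 CPM against 133.5 ± 11.7 CPM, a fold of 1.81 (log2 fold change 0.86, SE 0.21, edgeR adjusted p = 0.316). For miR-4521 the levels were 2383 ± 22.04 and 2869 ± 153.4 CPM, and for miR-758-3p, of the imprinted 14q32 region, 611.2 ± 27.4 and 742.7 ± 27.3 CPM. For miR-146b-3p they were 14.6 ± 8.08 and 38.6 ± 5.10 CPM. All of these except miR-148a-5p and miR-195-3p had an adjusted p of 0.595.

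On the lower side, miR-1914-5p was at 87.2 ± 2.36 CPM with DMSO and 43.6 ± 1.76 CPM with entinostat (SD, n = 2), a fold of 0.501 (log2 fold change -0.996, SE 0.22, edgeR adjusted p = 0.316). Its hairpin overlaps an exon of UCKL1 on the same strand (chromosome 20, 63941465 to 63941544, minus strand). The level of miR-760 was 977.6 ± 60.0 CPM against 720.9 ± 22.6 CPM, a fold of 0.737 (log2 fold change -0.44, SE 0.10, edgeR adjusted p = 0.316). The hairpin of miR-760 lies opposite an intron of BCAR3 (chromosome 1, 93846832 to 93846911, plus strand). The minor arm let-7e-3p, whose hairpin is in an intron of SPACA6 (chromosome 19, 51692786 to 51692864, plus strand), was at 143.8 ± 8.18 and 93.9 ± 5.20 CPM. The minor arm miR-92a-1-5p of the MIR17HG transcript (chromosome 13, 91351314 to 91351391, plus strand) was at 63.5 ± 4.10 and 35.01 ± 10.4 CPM. For miR-550a-5p, whose name covers 3 annotated hairpins, the levels were 87.2 ± 12.8 and 50.8 ± 12.0 CPM. These last 3 miRNAs had an adjusted p of 0.595. The likelihood ratio test called miR-148a-5p and miR-195-3p higher and miR-1914-5p and miR-760 lower.

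**Figure D3:**
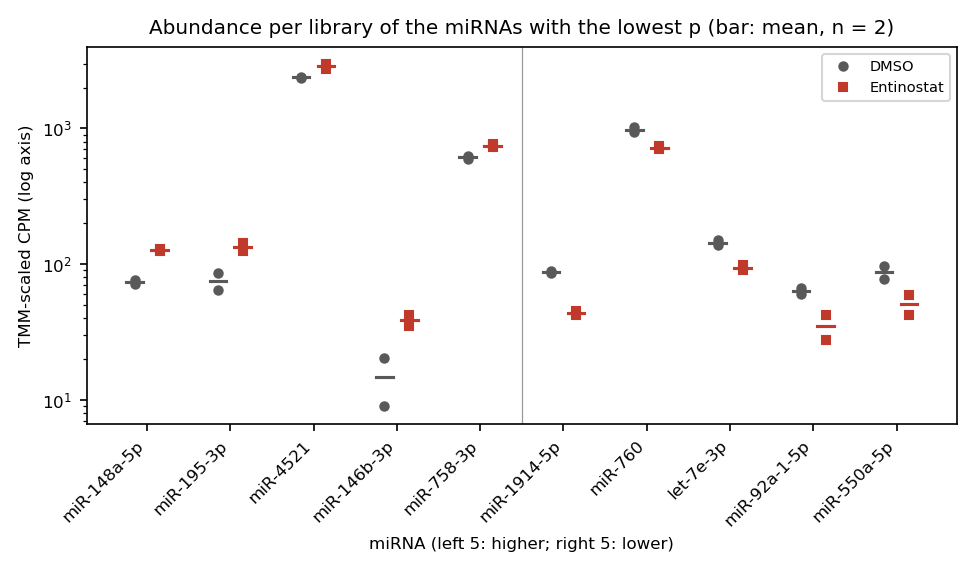
Abundance in TMM-scaled CPM on a log axis (y axis) of the 10 miRNAs with the lowest p (x axis), the 5 higher ones on the left; each symbol is 1 library, grey circles for DMSO and red squares for entinostat, and bars mark the mean of 2 libraries. The libraries of the treatments do not overlap for any of the 10, and none of these miRNAs passed an adjusted p of 0.05.

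Several well-studied miRNAs were chosen in advance, and none of them passed the threshold in the edgeR test either. The oncogenic miR-21-5p was at 15347 ± 1694 CPM with DMSO and 17467 ± 2401 CPM with entinostat (SD, n = 2), a log2 fold change of 0.19 (95% interval -0.07 to 0.44), which was 0.04 without entinostat replicate 1 and 0.32 without entinostat replicate 2. For miR-22-3p the levels were 1351 ± 34.1 and 1089 ± 136.3 CPM, a log2 fold change of -0.32 (-0.57 to -0.06; edgeR adjusted p = 0.595), and this miRNA was called lower without entinostat replicate 1 (-0.45) but stood at -0.19 without entinostat replicate 2 (edgeR adjusted p = 0.833). The hypoxia-induced miR-210-3p had 249.9 ± 6.81 and 301.3 ± 4.47 CPM, a log2 fold change of 0.27 (-0.02 to 0.57). The log2 fold change was 0.14 for miR-17-5p, 0.29 for miR-31-5p, 0.11 for miR-16-5p and 0.01 for let-7a-5p. The values were 0.09 for miR-17-5p without DMSO replicate 1 and 0.18 for miR-31-5p without entinostat replicate 2. Leaving out 1 library turned the sign for miR-16-5p and let-7a-5p, without entinostat replicate 2 for miR-16-5p (-0.04) and without DMSO replicate 1 or entinostat replicate 1 for let-7a-5p (-0.05 and -0.10). The epithelial miR-200c-3p was rare, at 29.1 ± 5.83 and 44.2 ± 2.69 CPM (log2 fold change 0.57, -0.13 to 1.28). Counts were too low for testing miR-34a-5p, a p53 target, with 12 and 4 counts with DMSO and 8 and 17 with entinostat. The same held for miR-205-5p, an epithelial miRNA, with 0 and 2 against 9 and 4 counts, and for miR-29b-3p, with 2 and 0 against 0 and 0 counts.

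None of the 20 tested miRNA families, clusters and sets was called (camera with a preset correlation, lowest adjusted p 0.272; with an estimated correlation, lowest adjusted p 0.797; fry, lowest adjusted p 0.239 for change in one direction and 0.112, in the miR-30 family, for change in either). In each of them 0 members were called over all tested miRNAs, and 0 were called adjusted over the list alone, except 1 in the miR-15/16 family, miR-195-3p (edgeR p adjusted over the list alone 0.0284). Medians of log2 fold changes below were all moved up by about 0.12 with upper quartile factors.

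The miR-23/27/24 clusters had the lowest camera p of all lists, though not the lowest fry p. All 8 tested members lay above 0 (median log2 fold change 0.13), among them miR-23a-3p at 7126 ± 661.4 CPM with DMSO and 8694 ± 1305 CPM with entinostat (SD, n = 2; log2 fold change 0.29, or 0.43 without entinostat replicate 1). Values for miR-27a-5p, miR-24-2-5p and miR-27b-3p were 0.26, 0.28 and 0.13. The camera adjusted p was 0.272, and 0.797 with an estimated correlation of -0.0724. That estimate lay below 0, so positive correlation between members does not account for the higher p. Of 8 miRNAs linked to p53 in earlier work, 7 lay above 0 (median 0.35, camera adjusted p = 0.272, and 0.797 with an estimated correlation, here -0.0459). They included miR-34c-5p (0.37) and miR-194-5p (0.35), and miR-192-5p lay at -0.20. The farthest of them, miR-145-5p, known from smooth muscle, rested on 9.45 ± 3.29 and 25.4 ± 12.5 CPM. Next came miR-1246 (0.88), with 23 and 2 counts with DMSO and 5 and 35 with entinostat. It also stood in the list of entries that overlap other RNA classes. All 6 tested members of the miR-181 family lay above 0 (median 0.13, camera adjusted p = 0.474), among them miR-181d-5p (0.28) and miR-181b-5p (0.13).

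In the let-7 family, known for its role in differentiation, 5 of 14 tested members lay above 0 and 9 below (median -0.08, or 0.03 with upper quartile factors; camera adjusted p = 0.474). Its members with the lowest p were the minor arms let-7e-3p (-0.60), let-7b-3p (-1.84), let-7c-3p (-0.34) and let-7d-3p (-0.56), of which let-7b-3p had no count in 1 entinostat library. Without entinostat replicate 1, camera with the preset correlation called the let-7 list lower and the p53-linked list higher. Neither list was called with an estimated correlation, which was 0.275 for let-7 and -0.143 for the p53-linked list. The negative value cannot be what removed the p53-linked call. The oncogenic miR-17~92 cluster and its paralogs had 11 of 16 members above 0 (median 0.13, camera adjusted p = 0.532). They included miR-106b-5p (0.53), miR-93-5p (0.19) and, below 0, miR-92a-1-5p (-0.90) and miR-25-5p (-0.28). In the miR-15/16 family, linked to cell cycle control, 6 of 9 members lay above 0 (median 0.11, camera adjusted p = 0.532), with miR-15b-3p at 0.58, miR-15b-5p at 0.22 and miR-424-3p at -0.48, or -0.87 without entinostat replicate 1.

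A list of miRNAs tied to histone deacetylase inhibition in earlier work had 12 of 21 members above 0 (median 0.03, camera adjusted p = 0.532). Its members with the lowest p were miR-22-3p (-0.32), miR-125a-5p (-0.23), miR-29a-3p (0.20) and miR-200c-3p (0.57). In the miR-99, miR-100 and miR-125 families and clusters 5 of 10 members lay above 0 (median 0.00480, camera adjusted p = 0.668), and miR-99b-3p was at -0.08. The median lay above 0 while the camera direction was down, and the same was true of the cluster of miR-183, miR-96 and miR-182. That cluster had 2 of 4 members above 0 (median 0.000766, camera adjusted p = 0.706), among them miR-182-5p (0.04), with miR-183-5p at -0.04. With size factors of the DESeq2 kind the medians of these lists lay below 0, at -0.000905 for miR-99, miR-100 and miR-125 and -0.00520 for the miR-183 cluster. The miR-30 family had 4 of 9 above 0 (median -0.03, or 0.09 with upper quartile factors; camera direction up, adjusted p = 0.925), including miR-30b-5p (0.30) and miR-30c-1-3p (-0.50). The cluster of miR-221 and miR-222 had 2 of 4 above 0 (median 0.04, camera adjusted p = 0.746), with miR-221-3p at 0.15 and miR-222-3p at -0.11.

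The imprinted DLK1-DIO3 clusters at 14q32 were widely expressed, with 71 listed members holding 3.37% and 3.38% of the counts with DMSO and 3.25% and 3.35% with entinostat. Of the 48 tested members, 24 lay above 0 and 24 below (median -0.00382, or 0.11 with upper quartile factors; camera adjusted p = 0.532). Their members of lowest p were miR-329-3p (-0.31), miR-433-3p (-0.29), miR-758-3p (0.29) and miR-541-3p (-1.09). The HOX-linked list of miR-10 and miR-196 had 1 of 6 above 0 (median -0.07, or 0.04 with upper quartile factors; camera adjusted p = 0.532). The abundant miR-615-3p, from the HOXC region, was at 13205 ± 540.0 and 11324 ± 1551 CPM (SD, n = 2; log2 fold change -0.22), and miR-10b-5p was at -0.10. Lung cancer-raised miRNAs had 12 of 20 above 0 (median 0.08, camera adjusted p = 0.668), with miR-155-5p at 0.54. Hypoxia-linked miRNAs had 5 of 7 above 0 (median 0.07, camera adjusted p = 0.532), with miR-193b-3p at 0.32, or 0.56 without entinostat replicate 1.

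Markers of other cell types and non-canonical entries were also followed. Neuronal miRNAs had 10 of 16 members above 0 (median 0.08, camera adjusted p = 0.532), with miR-9-5p at 0.18 and miR-128-3p at -0.15. The miR-34 and miR-449 family had 2 of 3 above 0 (median 0.36, camera adjusted p = 0.620), with miR-34b-3p at 0.36 and miR-449c-5p at -0.29. Mesenchymal and smooth muscle miRNAs had 3 of 3 above 0 (median 0.22, camera adjusted p = 0.474), with miR-143-3p at 0.22 and miR-218-5p at 0.07. Mirtrons, which are made from short introns, had 2 of 7 above 0 (median -0.16, camera adjusted p = 0.532), including miR-1226-3p (-0.27) and miR-877-5p (0.16). Entries that overlap other RNA classes had 4 of 9 above 0 (median -0.10 with a mean of 0.05, and a median of 0.02 with upper quartile factors; camera adjusted p = 0.620), including miR-1260a (-0.27) and miR-4286 (0.38).

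**Figure D4:**
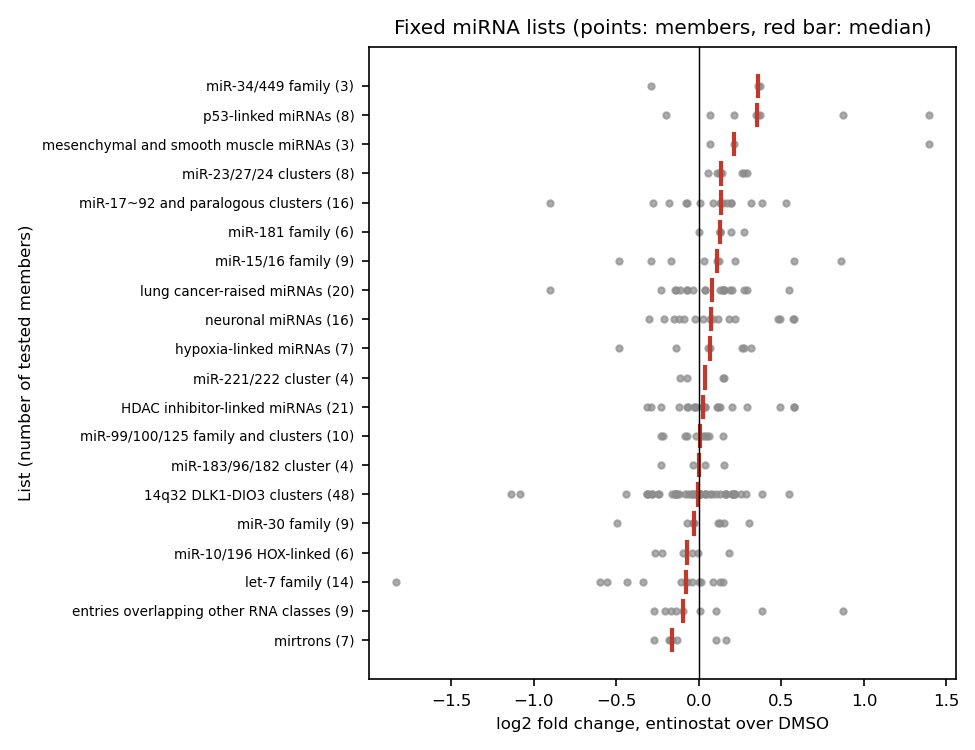
Log2 fold change of entinostat over DMSO (x axis) of the tested members of each of the 20 tested lists (y axis, number of members in brackets); each grey point is 1 miRNA and each red bar the median of its list. Medians run from -0.16 for mirtrons to 0.36 for the miR-34 and miR-449 family, none of the lists was called, and upper quartile factors moved the medians up by about 0.12.

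The other 7 lists had too few tested members for a test. In the miR-29 family 1 member passed the filter, miR-29a-3p at 728.0 ± 41.1 and 833.2 ± 14.8 CPM (SD, n = 2). The miR-200 family had 2 listed members and at most 0.00465% of a library's counts. The haematopoietic and erythroid list had 2 tested members, miR-155-5p and miR-486-5p (-0.06), and 0.0263 to 0.0307% of the counts. The hepatocyte and serum list also had 2, miR-194-5p and miR-192-5p, and 0.0255 to 0.0289%. Muscle miRNAs held at most 0.00164% of the counts with 0 tested members, and the cluster of miR-371, miR-372 and miR-373 had 1 listed and 0 tested members. The placental C19MC cluster had 0 listed members and was not analysed here.

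The 5p and 3p arms of one miRNA name did not move together in a detectable way. Arms were paired by name, and a name can cover several hairpins, whose arms are then pooled. Arms with a copy number in the name, such as miR-92a-1-5p, found no partner of that name and were left out. Across 92 hairpins with both arms tested, the log2 fold changes of the 5p and 3p arms had a Pearson r of 0.0628 (permutation p = 0.546) and a Spearman rho of 0.0198 (permutation p = 0.850). Both had a Benjamini-Hochberg adjusted p of 0.850 over the 2 tests. The signs matched in 48 hairpins (52.2%), and r was 0.00857 without the 2 hairpins whose 5p arm lay farthest from the median 5p arm. Hairpins extreme in the 3p arm alone, such as let-7b, stayed in. Discordant pairs included let-7b, with 0.15 for the 5p arm and -1.84 for the 3p arm, and miR-766, with -0.58 and 0.18, both chosen after their values were seen. This relation is across hairpins, which are not independent replicates. The hairpins of miR-365a and miR-365b entered separately with the same 3p counts. Over all tested miRNAs the median size of the log2 fold change was 0.150, against a median standard error of 0.176. With values this close to their error, an r near 0 does not exclude coupled arms. With both arms at 100 CPM or more, r was -0.0668 over 36 hairpins.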

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

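The crossed pairing and the arm pairs at 100 CPM or more were chosen after seeing the data. The count of 0 called miRNAs held with each scaling, with either filter, with DESeq2, limma-voom and the deposited CPM, without the 5 most abundant miRNAs and with a replicate block (25 at an unadjusted p under 0.05). The likelihood ratio test called 2 higher and 2 lower; it leaves out the uncertainty of each dispersion. Leaving out each replicate gave 0 to 3 called higher and 0 to 3 called lower, all of them without entinostat replicate 1. These were miR-193b-3p, miR-23a-3p and miR-342-3p higher and miR-22-3p, miR-424-3p and miR-543 lower (lowest adjusted p 0.0163). Spread then came from the DMSO pair alone, and the lone library was assumed to vary like it. Called lists ranged from 0 to 2 over the same fits. At an adjusted p under 0.1, upper quartile factors gave 2 miRNAs (lowest adjusted p 0.0973), no filter 2 (0.0933), the deposited CPM with all miRNAs 3 (0.0749) and the likelihood ratio test 4; leaving out a library gave 10 without entinostat replicate 1, 2 without DMSO replicate 2 (0.0591), 1 without entinostat replicate 2 (0.0687) and 0 without DMSO replicate 1. Counts higher and lower at an unadjusted p under 0.05 were 38 and 6 with upper quartile factors, 22 and 23 without a filter, 3 and 8 with DESeq2, and 24 and 25 with the deposited CPM of all miRNAs. The fits without a filter, with DESeq2 and with the deposited CPM of all miRNAs covered 826 miRNAs rather than 401. Without entinostat replicate 1 there were 27 higher, and without entinostat replicate 2 there were 23 lower. Same-numbered libraries had deviations from their group means correlated at -0.124 across miRNAs, and no label says what a number marks; with the numbers crossed, 0 were called and 32 had an unadjusted p under 0.05. The replicate block changed no call, among lists included. Log2 fold changes reversed for miR-30c-5p (0.0375) and miR-125b-5p (0.0439) with upper quartile factors, which shifted all miRNAs, and for let-7a-5p with a mean CPM of 10 or more (-0.00130). Over fits without 1 replicate, let-7a-5p ranged from -0.10 to 0.11 and miR-16-5p from -0.0398 to 0.23; among others, values also moved by over 1.5 times for miR-99a-5p (0.00485 to 0.0862), miR-30c-5p (-0.12 to -0.03), miR-125b-5p (-0.13 to -0.02), miR-146b-3p (0.92 to 2.11) and miR-92a-1-5p (-1.20 to -0.59). For arm pairs, r was -0.0668 with both arms at 100 CPM or more, 0.0947 without the fixed clusters and 0.0502 with the replicate block; a mean CPM of 10 removed no pair. The cause of these reversals was otherwise not tested. Summing repeated names was not run, since names did not repeat. Of the 97 miRNAs of 1000 CPM or more, 91 to 97 had intervals inside 1.5-fold over the alternatives with an interval. The fit without the 5 most abundant gave 91, but those 5 were not in it, so its total was below 97. Precision is lower for rarer miRNAs, with 295 of 401 intervals inside 2-fold.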

Other observations

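The tests on let-7 3p arms were chosen only after the result was seen, and so was the comparison of GC content without single libraries. Of the other ways to split the 4 libraries into 2 and 2, replicates 1 against 2 gave 8 miRNAs at an unadjusted p under 0.05 (edgeR, lowest adjusted p 0.994). DMSO replicate 1 and entinostat replicate 2 against the other two gave 23 (lowest adjusted p 0.276), and the treatments gave 27 (0.316). DMSO replicate 1 and entinostat replicate 2 were also the deeper libraries, with totals of 938559 and 753104 counts. DMSO replicate 2 and entinostat replicate 1 had 561485 and 547875, so that split is not independent of depth. With 3 splits, a share under 0.05 cannot be reached.

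All 5 tested 3p arms (let-7a, b, c, d and e) had log2 fold changes below 0 with each scaling and without each library (median -0.56 over all 4), and their summed deposited level was 499.7 and 546.8 CPM with DMSO against 394.3 and 345.2 CPM with entinostat. The 8 tested let-7 5p arms ranged from -0.11 to 0.15, with 5 above 0, and the difference between the arms was not tested. Against a lower yield of minor 3p arms in general, the other 35 minor 3p arms had a median of 0.0385 (95% bootstrap interval -0.0547 to 0.146). Against a single deviating library, the log2 ratio of the summed level was -0.408 or lower without each library in turn. With replicates 1 against 2, 2 of the 5 arms lay below 0, and with the split that follows depth 1 did. The sign of those splits is arbitrary, so most arms shared a direction there too. For the 4 arms with counts in all libraries, the median was -0.455 before and -0.484 after the GC trend described below was removed. Both of these medians were taken from log2 levels rather than the fit. A trend that small could hardly have moved them, so this check decides little. The arms were picked because they lay lower, no list test over all 4 libraries called let-7, and 2 libraries per group are few, so a treatment effect on let-7 passenger strands is only a hypothesis, and selection by chance stays open.

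Log2 fold changes fell with the GC content of the hairpin arm's side of the precursor (Spearman rho -0.157 across 400 miRNAs, permutation p = 0.00139, and -0.235 across 237 of 100 CPM or more; miRNAs are not independent replicates). Differences of replicate 2 minus replicate 1, an order that makes their sign arbitrary, had a rho of -0.170 within DMSO (permutation p = 0.000580, and -0.173 at 100 CPM or more) and of 0.0781 within entinostat (permutation p = 0.121), and the slope difference within DMSO, -0.0296 log2 units per 10 points of GC (95% bootstrap interval -0.0686 to 0.0134), was as large in size as that between treatments, -0.0272 (-0.0590 to 0.0028). This is consistent with GC-dependent recovery that differs between libraries; rho was -0.0614 without DMSO replicate 1, -0.0773 without entinostat replicate 1, -0.190 without DMSO replicate 2 and -0.155 without entinostat replicate 2. Once the linear trend was removed, 4 of the 4 miRNAs of lowest p kept over 95% of their log2 fold change. The trend was thus too small to account for fold changes of that size. With a slope this small the outcome was nearly fixed, so it says nothing about other effects linked to GC content. A treatment effect on GC-rich miRNAs stays open.

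Minor arms turn over faster than major arms in some cells, so they may respond first within 8 h. Across 92 hairpins, the mean absolute ratio of log2 fold change to its standard error was no higher in minor than in major arms, with a difference of 0.00127 (95% bootstrap interval -0.236 to 0.225, sign-flip permutation p = 0.990). The other splits of the libraries gave 0.196 (0.0533 to 0.342, permutation p = 0.0105) and -0.194 (-0.366 to -0.0243, permutation p = 0.0351). The p across hairpins thus leaves out the spread between libraries, and a general early response of minor arms was not detectable beside the other splits. The ratio divides by a standard error that is larger for rarer miRNAs, so equal ratios leave open a larger change in minor arms.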
